A study of Mus musculus with 4 samples.

How the data were processed

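Whole lung of adult, age-matched mice was profiled on 4 Affymetrix expression arrays, 2 from wild-type (WT) C57/BL6 mice and 2 from mice labelled SCD, for sickle cell disease. Per the labels' protocols, total RNA was extracted with TRIzol and labelled with biotin through a 3' in vitro transcription kit. The SCD mouse line, the sex of the animals, the time of collection, RNA quality values and any batch are not given in the sources used here. Groups were taken from the sample titles. The labels speak of 2 lungs per genetic group. No label states further that each array is a separate animal, so that the limma p-values of genes measure the spread between these samples.

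The deposited values are read as log2 expression values, 1 per probe set and array. Per the submitters' processing notes, Affymetrix Expression Console, Partek and RMA (robust multi-array average) were used; their versions, roles and order are not given. The log2 scale is not written in the deposited table and was read from the values, which ran from 1.72 to 19.93. The value was identical on all 4 arrays for 192 transcript clusters, 21 named genes among them and many of them bright, so that no direction can be read for these. Array medians over all probe sets were 5.73 and 5.70 for WT and 5.68 and 5.67 for SCD. The number of arrays limits the precision of every value.

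The table held 72688 probe sets, of which 6732 were controls and 65956 were transcript clusters. The platform annotation, with symbols updated through the RefSeq gene table of the GRCm38.p6 assembly, paired 31258 probe sets with 1 gene, 1492 with several genes and none with the other 33206 transcript clusters. Each gene was represented by its probe set with the highest mean over all 4 arrays, which gave 30701 genes, 442 of them with several probe sets. The RefSeq table held 30699 of these symbols, 19228 of them protein-coding, and was used for names and for the order of neighbouring genes only. No filter on dim probe sets was applied.

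SCD was compared with WT with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend and group as the only term. Tests were two-sided, and p-values were adjusted with the Benjamini-Hochberg method over all 30701 genes, with a threshold of 0.05. Differences are SCD minus WT on the log2 scale, with the moderated standard error (SE); group spreads are standard deviations (SD). The 37 gene lists, written before the data were examined, were tested with camera at a preset correlation of 0.01 with the same intensity trend in the variance, adjusted over the lists. The trend was listed beforehand among the choices for the lists, but the test as written did not name it for camera. The first run left it out and gave 22 lists. It was put in after that result was known, which added alveolar type 1 cells and immediate early genes. At the preset correlation, camera weighs a list's genes against all other genes, so that its p-values rest on the spread over genes and not between animals. Camera with an estimated correlation, which rests on the 2 residual degrees of freedom, was run beside it. Fry, which asks whether a list's genes move on balance one way, was also run.

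Named genes were chosen by a rule fixed before the data were examined. It took every measured globin gene, the 12 largest increases and the 12 largest decreases past the threshold without predicted or clone-derived names, and up to 4 members with the smallest p of each list discussed. It also took Hmox1, Hp, Hpx, Vcam1, Edn1, Nos3, Arg1, Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Nnt and H2-Ea whatever their values. Ddx3y had no probe set of its own. Some genes under the rule that did not change a list's description are not printed. Other genes named in the text were chosen after their values were seen.

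The scripts were tested on simulated data for the SCD against WT comparison, with 30701 genes in each of 5 simulations. The fit recovered 14.0% of genes changed by 1 on the log2 scale and 84.6% of genes changed by 2, with 4 false calls on average and 7 at most. Without any changed gene it called 0 genes and 0 lists. Simulated genes varied independently of each other, with variances drawn from the fit itself. The 0 lists therefore do not show how camera at the preset correlation behaves where genes are correlated. Alternatives fixed beforehand were the replicate number as a block, no intensity trend, filters on the dimmest 25% and 50% of genes, the mean of a gene's probe sets, repeated quantile normalization, equal array medians, array weights, robust eBayes, other thresholds, every probe set, camera on ranks, and each array left out in turn. Cyclic loess, removal of the shift of the exon controls, omission of genes with identical values and protein-coding genes alone were added after seeing the data. Marker sets for capillary, pan-endothelial, ciliated, secretory and hepatocyte genes and for both arms of the clock were drawn up later still, with values of many members known. They are described by counts and medians. Exact permutation tests run between the capillary and pan-endothelial sets and between the clock arms are not used, since a test on genes chosen with their values known decides nothing. A general shift was weighed for the clock genes first through Arntl and Npas2 alone and then through the median of the ROR-driven genes (-0.122), neither of which decides it. It was weighed last through the higher clock genes with the exon control shift removed, whose outcome was fixed by differences already known. Neighbouring genes were tested with 10000 permutations in Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6; figures were drawn with matplotlib 3.10.9. Probe sets that name no gene or several genes were not used in the gene comparison.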

Results

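Gene expression was measured in whole lung of adult, age-matched WT and SCD mice, with 2 arrays in each group. Across 30701 genes, the Pearson correlation was 0.992 between the WT arrays and 0.995 between the SCD arrays. Between groups it ranged from 0.986 to 0.988; these correlations are across genes, which are not independent replicates. The comparison asked which genes and gene groups differ between the lungs of SCD and WT mice. Differences below are SCD minus WT on the log2 scale ± SE from limma, with n = 2 arrays per group.

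The largest increases in SCD lung included Fgg and Fga, Cxcl9, Alas2, Ppbp and antibody genes, and the largest decreases included Aplnr, Glp1r, Kit, Tek and Eln. Fgg, which encodes the fibrinogen gamma chain, rose by 5.22 ± 0.14 (adjusted p = 0.0023), from 5.80 ± 0.20 to 11.03 ± 0.11 (mean ± SD). Fga, the fibrinogen alpha chain, rose by 3.21 ± 0.11, whereas Fgb, the beta chain, named after its value was seen, did not pass (0.10 ± 0.13). A2ml1, a protease inhibitor gene, rose by 5.15 ± 0.15, Apol11b by 4.83 ± 0.12 and Gdpd3 by 4.51 ± 0.14. The interferon-induced chemokine gene Cxcl9 rose by 3.73 ± 0.20, the platelet chemokine gene Ppbp by 3.31 ± 0.19 and Speer4c by 3.70 ± 0.16. Antibody genes were also among the largest increases, with Ighv1-9 at 4.05 ± 0.13, Jchain, the joining chain of secreted antibodies, at 3.30 ± 0.11, and Ighg2b at 3.01 ± 0.16. The WT means of Fgg, Fga, A2ml1, Apol11b, Gdpd3, Cxcl9 and Speer4c lay above the median of the antigenomic background probes (3.32) but below that of the intron controls (6.48 on the WT arrays), so that the sizes of these increases may be lower bounds. The largest decreases were those of Aplnr, the apelin receptor, which fell by 3.31 ± 0.21 (9.89-fold lower; adjusted p = 0.0069), and Glp1r, the glucagon-like peptide receptor, which fell by 3.31 ± 0.11. Rnf144a fell by 2.19, the receptor kinase gene Kit by 2.18, the angiopoietin receptor gene Tek by 1.94 and the endothelial phosphatase gene Ptprb by 1.82. Eln, which encodes elastin, fell by 1.88 and the matrix gene Hmcn1 by 1.91. Fabp1, Fmo1, Ifi213 and Erdr1 also fell, with differences of -1.96, -1.73, -1.61 and -1.83. The other probe set of Erdr1 moved the same way, with a difference of -1.92.

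**Figure D1:**
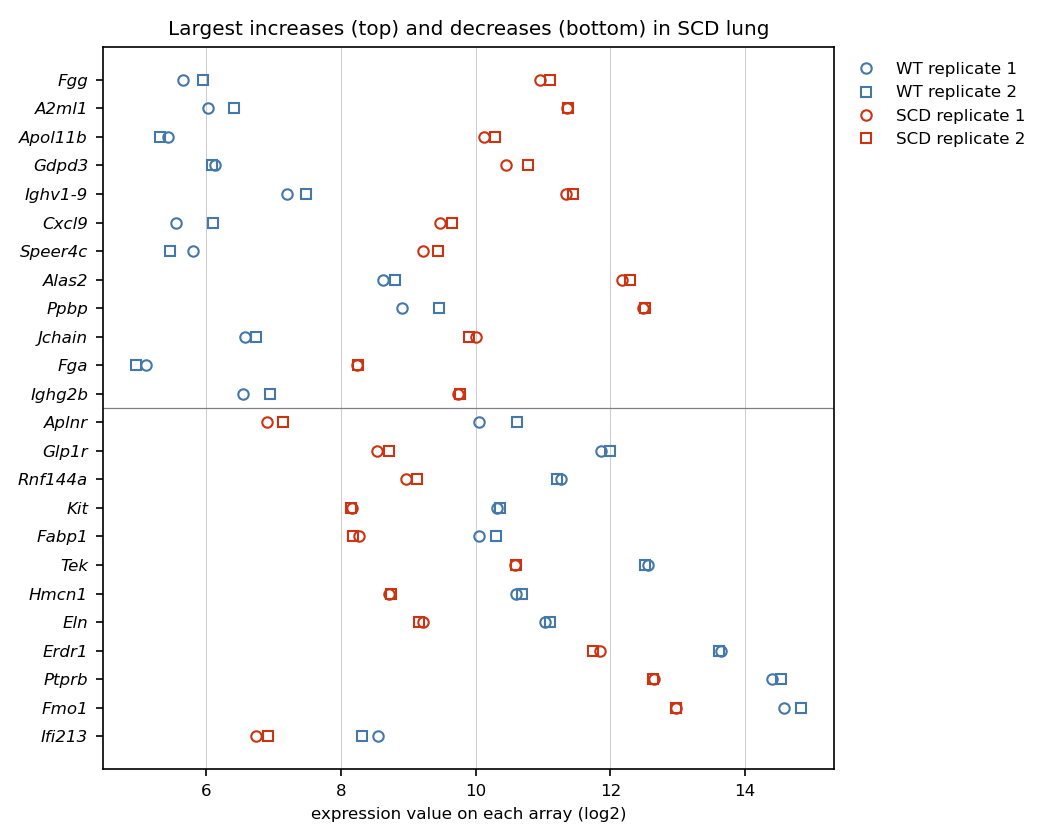
Log2 expression value on each of the 4 arrays (x axis) for the 12 largest increases and the 12 largest decreases (y axis), with circles for replicate 1 and squares for replicate 2 of WT and SCD. For every gene shown, both SCD arrays lie on the same side of both WT arrays; Fgg has a mean of 5.80 in WT and 11.03 in SCD lung.

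In all, 949 genes passed an adjusted p of 0.05, 754 higher and 195 lower in SCD lung, so that 79.5% of the calls were higher. Of these, 438 higher and 72 lower genes differed by at least 1 on the log2 scale. Protein-coding genes made up 498 of the higher and 138 of the lower calls, and 249 calls had predicted or clone-derived names. Control probes also differed between the groups. The median of the spiked hybridization controls was 0.17 higher in SCD than in WT arrays, that of the exon controls 0.20 higher and that of the intron controls lower, with a difference of -0.18. Exon control medians were 10.01 and 10.15 on the WT arrays and 10.26 and 10.29 on the SCD arrays. With the shift of the exon controls taken off every SCD value, which moved the median of all genes from 0.0019 to -0.19, 524 genes were higher and 573 lower, or 47.8% higher; taking 1 amount off every SCD value lowers this share by itself. Without SCD replicate 1 or without SCD replicate 2, limma called 0 genes, with 3302 and 3267 genes at an unadjusted p under 0.05; without WT replicate 1 it called 508.

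Some erythroid genes rose in SCD lung. Alas2, the erythroid enzyme that starts heme synthesis, rose by 3.52 ± 0.10 (11.5-fold), and Fech, which inserts iron into heme, by 2.21 ± 0.10. Mkrn1 rose by 1.21 and the mitochondrial iron importer gene Slc25a37 by 1.23. Of 39 genes of erythroid precursors and reticulocytes, 9 rose, 0 fell and 30 did not pass; adjusted over the list alone, 13 rose. The transcription factor genes Gata1 (0.03 ± 0.12) and Klf1 (0.28 ± 0.15), named after their values were seen, did not pass. The list passed camera (adjusted p = 3.37e-07, and adjusted p = 0.135 with an estimated correlation). Among the 6 globin genes measured alone, Hbq1a rose by 2.70 ± 0.10 and Hba-x by 1.86 ± 0.13. Hbb-bh1 (0.96 ± 0.19), Hbq1b (0.65 ± 0.15), Hbb-bh2 (0.26 ± 0.14) and Hbb-y (-0.10 ± 0.18) did not pass; adjusted over the list alone, 4 rose. The globin list passed camera (adjusted p = 7.92e-05, and adjusted p = 0.135 with an estimated correlation). It rests on dim probe sets: the WT means of all 6, from 3.92 (Hbb-bh1) to 6.41 (Hbb-y), lay below the intron control median of the WT arrays (6.48). The adult alpha and beta globin genes shared their probe sets, and these held identical values on all 4 arrays, so that they give no direction and no check of the labels.

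Genes of heme and iron handling rose in 5 of 36 cases and fell in 1, with 30 not passing (7 up and 1 down adjusted over the list alone). The siderophore-binding protein gene Lcn2 rose by 2.64 ± 0.09, the ferrireductase gene Steap4 by 1.54 and the ferritin receptor gene Ncoa4 by 1.35, while Bmp6, an inducer of hepcidin, fell by 1.45 ± 0.14. This list passed camera (adjusted p = 0.0029, and adjusted p = 0.231 with an estimated correlation). The heme oxygenase gene Hmox1 (0.68 ± 0.15; adjusted p = 0.106), the haptoglobin gene Hp (0.08 ± 0.08) and the hemopexin gene Hpx (0.33 ± 0.12) did not pass.

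Neutrophil genes rose in 12 of 32 cases and fell in 0, with 20 not passing and 19 up adjusted over the list alone. The calgranulin genes S100a8 and S100a9 rose by 2.62 ± 0.16 and 2.51 ± 0.11, and the lactoferrin gene Ltf by 1.67 ± 0.11. The neutrophil list passed camera (adjusted p = 8.21e-15, and adjusted p = 0.135 with an estimated correlation). Of 30 genes of monocytes and interstitial macrophages, 6 rose, 0 fell and 24 did not pass (12 up adjusted over the list alone). Ly6c2 (1.55 ± 0.05), Ly6c1 (1.53 ± 0.06), the chemokine receptor gene Ccr2 (1.11 ± 0.10) and Lyve1 (0.92 ± 0.10) were among those that rose. Ly6c1 is also in the list of genes known to differ between inbred strains, and Lyve1 in the endothelial list. Camera gave an adjusted p of 3.37e-07, and an adjusted p = 0.135 with an estimated correlation. Alveolar macrophage genes went both ways: of 25, 4 rose and 2 fell with 19 not passing (6 up and 5 down adjusted over the list alone). The scavenger receptor gene Marco fell by 1.48 ± 0.10, while the elastase gene Mmp12 rose by 1.41 ± 0.13 and Car4 by 1.18 ± 0.09; the list did not pass (adjusted p = 0.729; downward by the test, median of -0.068, mean of 0.001).

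T and NK cell genes rose in 7 of 32 cases and fell in 0, with 25 not passing and 13 up adjusted over the list alone. The chemokine gene Ccl5 rose by 1.76 ± 0.16, the granule genes Nkg7 and Gzmk by 1.18 and 1.22, and the NK receptor gene Klrd1 by 1.11 (camera adjusted p = 8.11e-07, and adjusted p = 0.135 with an estimated correlation). Among 27 genes of dendritic cells and MHC class II, 6 rose, 0 fell and 21 did not pass (7 up and 2 down adjusted over the list alone). Ccl17 rose by 2.13 ± 0.18, Bst2 by 1.24, H2-Eb1 by 1.21 and H2-Ab1 by 0.96 (camera adjusted p = 0.0023, and adjusted p = 0.266 with an estimated correlation). Of 25 platelet and megakaryocyte genes, 5 rose, 0 fell and 20 did not pass, with 5 up adjusted over the list alone; Pf4, platelet factor 4, rose by 1.13 ± 0.15 and the coagulation factor gene F5 by 1.07 (camera adjusted p = 4.4e-05, and adjusted p = 0.135 with an estimated correlation). Of 26 genes of B cells and plasma cells, Jchain and Ighm, the IgM heavy chain (0.78 ± 0.08), rose and 24 did not pass (2 up and 1 down adjusted over the list alone). That list did not pass (adjusted p = 0.993); its test pointed down while its median was 0.002 and its mean 0.112, and Fcer2a (-0.75 ± 0.12) and Ighg1 (0.40 ± 0.11) did not pass. In the list of mast cells, basophils and eosinophils, Kit fell and 18 of 19 genes did not pass, Hdc (1.15 ± 0.20) among them (3 up and 2 down adjusted over the list alone, camera adjusted p = 0.612).

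Among inflammatory genes, Ccl8 rose by 2.81 ± 0.13, the interleukin genes Il1b and Il33 by 2.65 ± 0.19 and 2.39 ± 0.10, and Ccl9 by 2.16 ± 0.11. Of 46 NF-kB cytokine and receptor genes, 7 rose, 0 fell and 39 did not pass, with 20 up adjusted over the list alone (camera adjusted p = 5.33e-11, and adjusted p = 0.135 with an estimated correlation). Interferon-stimulated genes rose in 7 of 49 cases and fell in 0, with 42 not passing and 17 up adjusted over the list alone. The antiviral genes Rsad2 and Oas1a rose by 2.14 ± 0.19 and 1.32 ± 0.13 (camera adjusted p = 8.11e-07, and adjusted p = 0.135 with an estimated correlation). Of 33 complement genes, 4 rose, 1 fell and 28 did not pass (9 up and 1 down adjusted over the list alone). C4b rose by 1.45 ± 0.09, the factor B gene Cfb by 1.21 and C7 by 0.77, whereas Hc, the gene of complement component C5, fell by 0.38 ± 0.06 (camera adjusted p = 3.9e-04, and adjusted p = 0.164 with an estimated correlation). Hc missed the threshold in limma without the intensity trend and with equal array medians (adjusted p of 0.17 and 0.0981), among other settings.

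Endothelial genes moved in both directions, mostly downward. Of 37, 10 fell, 4 rose and 23 did not pass (18 down and 6 up adjusted over the list alone). Beside Tek, Ptprb and Aplnr, the capillary lipase anchor gene Gpihbp1 fell by 1.56 ± 0.09, while Mmrn2 rose by 1.66 ± 0.10 (camera adjusted p = 1.7e-05, downward, and adjusted p = 0.305 with an estimated correlation). In the list of endothelial activation, adhesion and coagulation, 3 of 38 genes rose, 2 fell and 33 did not pass (11 up and 4 down adjusted over the list alone). Tissue factor, F3, rose by 1.35 ± 0.10 and the plasminogen activator gene Plat by 1.06, and the scavenger receptor gene Cd36 fell by 0.66 ± 0.05 (camera adjusted p = 2.5e-04, and adjusted p = 0.135 with an estimated correlation). Vcam1 (0.33 ± 0.09; adjusted p = 0.161) and the endothelin gene Edn1 (0.68 ± 0.12; adjusted p = 0.056) did not pass. Among 38 genes of nitric oxide, arginine and vasoactive signalling, 3 rose, 1 fell and 34 did not pass (7 up and 6 down adjusted over the list alone). The natriuretic peptide gene Nppa rose by 2.88 ± 0.13, the tetrahydrobiopterin synthesis gene Gch1 by 1.32 and Ddah1 by 0.93, and the BMP receptor gene Bmpr2 fell by 0.69 ± 0.06. The list did not pass camera (adjusted p = 0.993; upward by the test, with a median of -0.032) but passed fry (adjusted p = 0.044). Nos3 (0.07 ± 0.11) and Arg1 (-0.17 ± 0.14) did not pass. Hypoxia and glycolysis genes rose in 4 of 39 cases and fell in 2, with 33 not passing (8 up and 3 down adjusted over the list alone). Bnip3l rose by 1.00 and Ndrg1 by 0.90, while Hilpda and Epas1 fell, with differences of -1.09 and -0.36 (camera adjusted p = 0.0013, and adjusted p = 0.141 with an estimated correlation). Epas1 missed the threshold in limma without the intensity trend and with equal array medians (adjusted p of 0.185 and 0.0946), among other settings.

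**Figure D2:**
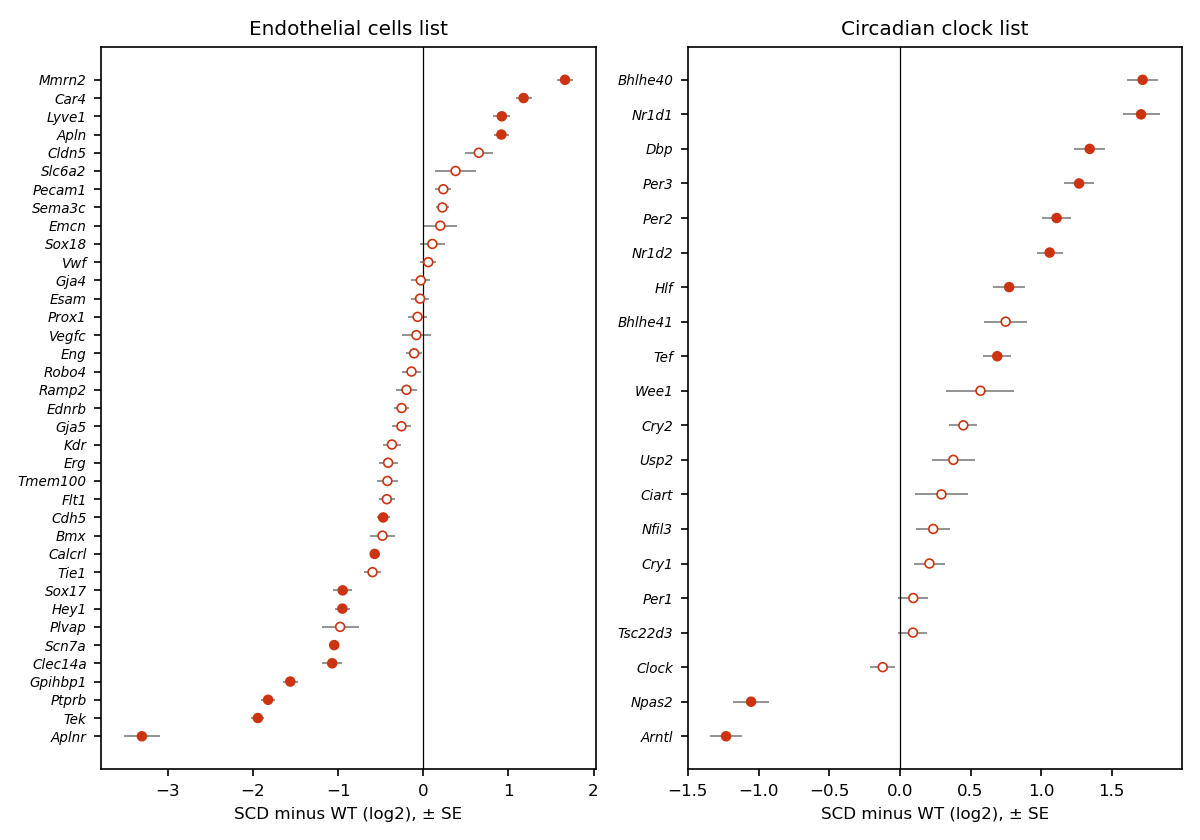
SCD minus WT difference ± SE (log2, x axis) for each measured gene (y axis) of the endothelial list and the circadian clock list, with filled points for genes past an adjusted p of 0.05 and open points for the others. Aplnr lies at -3.31 and Mmrn2 at 1.66; Arntl lies at -1.23 and Bhlhe40 at 1.72.

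Among airway genes, the antimicrobial lectin gene Reg3g rose by 2.71 ± 0.11, Bpifb1 by 2.28 ± 0.14, the mucin gene Muc5b by 1.43 ± 0.09 and the cilium gene Rsph1 by 1.29 ± 0.08. Of 30 club and ciliated cell genes, 13 rose, 0 fell and 17 did not pass, with 21 up adjusted over the list alone (camera adjusted p = 7.24e-16, and adjusted p = 0.135 with an estimated correlation). The club cell genes Scgb1a1 (0.00 ± 0.04), Cyp2f2 (-0.08 ± 0.05) and Scgb3a2 (0.22 ± 0.05) were among those that did not pass. A probe set shared by Cyp2a5, also of the list, and Cyp2a4 rose by 3.92 ± 0.16 in limma over every probe set. Alveolar type 2 and surfactant genes went both ways: 2 of 30 rose (Chil1 and Lrp2, at 0.57 and 0.74), 4 fell (among them Egfl6, by 0.89 ± 0.13) and 24 did not pass (4 up and 6 down adjusted over the list alone, camera adjusted p = 0.088). Both increases missed the threshold in limma with the exon control shift removed (adjusted p of 0.069 for Chil1 and 0.0505 for Lrp2). Among 25 alveolar type 1 genes, 3 rose, 0 fell and 22 did not pass (8 up and 1 down adjusted over the list alone), with the sodium channel genes Scnn1a and Scnn1g at 0.84 and 1.03 and Igfbp2 at 0.91, and Akap5 (-0.63 ± 0.11) not passing. Camera gave an adjusted p of 0.039 for that list, but 0.062 without the intensity trend and an adjusted p = 0.498 with an estimated correlation. Extracellular matrix genes rose in 5 of 51 cases and fell in 4, with 42 not passing (11 up and 15 down adjusted over the list alone). Beside Eln, the collagen gene Col3a1 fell by 1.11 ± 0.10, while the metalloproteinase inhibitor gene Timp3 rose by 1.28 ± 0.08 and the fibronectin gene Fn1 by 0.94 ± 0.07 (camera adjusted p = 0.106). Of 24 smooth muscle and pericyte genes, Cnn1 rose by 0.96 ± 0.13 and 23 did not pass (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.293). Cnn1 missed the threshold in limma without the intensity trend and with the exon control shift removed (adjusted p of 0.0524 and 0.0549). Acta2 (0.74 ± 0.13) did not pass.

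Heat shock and unfolded protein response genes rose in 14 of 29 cases and fell in 0, with 15 not passing and 21 up adjusted over the list alone. The chaperone genes Hsph1, Hspa4l, Hsp90aa1 and Chordc1 rose by 2.11 ± 0.08, 1.49 ± 0.10, 0.97 ± 0.07 and 1.00 ± 0.08 (camera adjusted p = 7.24e-16, and adjusted p = 0.135 with an estimated correlation). Of 29 NRF2 targets and antioxidant enzymes, 4 rose, 0 fell and 25 did not pass (9 up and 1 down adjusted over the list alone); Gclc, which makes the rate-limiting subunit of glutathione synthesis, rose by 1.97 ± 0.08 and the epoxide hydrolase gene Ephx1 by 1.47 (camera adjusted p = 3.37e-07, and adjusted p = 0.329 with an estimated correlation). Glucocorticoid-responsive genes rose in 7 of 23 cases and fell in 0, with 16 not passing and 10 up adjusted over the list alone. The metallothionein genes Mt2 and Mt1 rose by 2.62 ± 0.21 and 1.68 ± 0.15 and the cell cycle inhibitor gene Cdkn1a by 2.25 ± 0.12 (camera adjusted p = 2.49e-08, and adjusted p = 0.135 with an estimated correlation). None of 33 immediate early genes passed over all genes (0 up adjusted over the list alone), with Ptgs2 at 0.78 ± 0.15. The list had a camera adjusted p of 0.043, which was 0.052 without the intensity trend, and an adjusted p = 0.247 with an estimated correlation.

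Circadian clock genes went both ways. Of 20, 8 rose, 2 fell and 10 did not pass (10 up and 2 down adjusted over the list alone). Bhlhe40 rose by 1.72 ± 0.11, Nr1d1 by 1.71 ± 0.13, Dbp by 1.34 and Per3 by 1.27, while Arntl and Npas2, named after their values were seen, fell by 1.23 ± 0.11 and 1.05 ± 0.12 (camera adjusted p = 1.2e-06, and adjusted p = 0.135 with an estimated correlation). No cell cycle gene of 44 passed in limma over all genes or adjusted over the list alone (0 and 0); the proliferation marker Mki67 stood at 0.44 ± 0.10 with an unadjusted p of 0.0066 (camera adjusted p = 0.489). Lipid and cholesterol synthesis genes fell in 2 of 24 cases, Acly and Acaca (both -0.66), and rose in 0, with 22 not passing (3 down adjusted over the list alone). Both decreases missed the threshold with equal array medians (adjusted p of 0.054 and 0.061). The list passed camera (adjusted p = 0.0031, downward, and adjusted p = 0.305 with an estimated correlation). Xenobiotic metabolism genes rose in 5 of 29 cases and fell in 1, with 23 not passing (8 up and 5 down adjusted over the list alone). Cyp2b10 rose by 1.01 and Sult1d1 by 1.24, and Fmo1 fell (camera adjusted p = 0.105).

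Of 29 cardiac muscle genes, 4 rose, 0 fell and 25 did not pass, with 12 up adjusted over the list alone. Nppa rose, as did the atrial myosin light chain gene Myl7 (1.20 ± 0.10), Csrp3 (0.69) and Cox8b (0.83); Csrp3 and Cox8b missed the threshold with the exon control shift removed (adjusted p of 0.066 and 0.073). The list passed camera (adjusted p = 1.44e-07, and adjusted p = 0.135 with an estimated correlation). Adipose genes fell in 4 of 20 cases and rose in 0, with 16 not passing and 5 down adjusted over the list alone. Car3 fell by 1.35 ± 0.12, Adipoq by 1.33 ± 0.14, Fabp4 by 1.22 ± 0.10 and Retn by 0.94 ± 0.14 (camera adjusted p = 1.6e-05, downward, and adjusted p = 0.164 with an estimated correlation). Skeletal muscle genes gave 0 calls among 24 in limma over all genes and 0 adjusted over the list alone, with Eno3 at 0.35 ± 0.11 and an unadjusted p of 0.026 (camera adjusted p = 0.372). In the list of mesothelium, thymus and oesophagus, the keratin gene Krt8 rose by 1.48 ± 0.18, Upk3b fell by 1.03 ± 0.11 and 21 of 23 genes did not pass (2 up and 3 down adjusted over the list alone, camera adjusted p = 0.164).

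Among 9 sex-linked genes, limma called 0 over all genes and 0 adjusted over the list alone (camera adjusted p = 0.448). Xist, the transcript of the inactive X chromosome, had a mean of 16.77 in WT and 16.79 in SCD lung. The Y-linked genes Eif2s3y (4.94 and 4.86), Kdm5d (4.47 and 4.39) and Uty (4.64 and 4.54) and Sry (8.27 and 8.05) had unadjusted p-values of 0.55, 0.49, 0.44 and 0.31 in limma. Xist lay far above the exon control medians (10.08 in WT and 10.28 in SCD). Eif2s3y, Kdm5d and Uty lay below the intron control medians (6.48 and 6.29), while Sry lay above them. Apart from Sry, these values are those of female lung in both groups and argue against a sex difference between them. Levels of different probe sets cannot be ranked closely against each other. Of 23 genes known to differ between inbred strains, Ly6c1 and C4a (0.82 ± 0.10) rose, Trim12a fell by 0.80 ± 0.09 and 20 did not pass (3 up and 2 down adjusted over the list alone, camera adjusted p = 0.324). Camera asks for a shift in 1 direction, while strain differences can go either way, so its result does not speak against them. Fry regardless of direction gave an adjusted p of 0.000582, but also 0.00569 for skeletal muscle, which held 0 calls. A further 5 members lay only on shared probe sets. In limma over every probe set, 1 shared by Ifi202b, a member of the list, and Ifi205 rose by 1.52 ± 0.19 (adjusted p = 0.048). Shared probe sets of Mup genes other than the listed Mup1 fell, with differences of -3.08 ± 0.16 and -3.05 ± 0.13 (adjusted p of 0.011 and 0.0087). Nnt (-0.28 ± 0.10; adjusted p = 0.251) and H2-Ea (0.13 ± 0.18; adjusted p = 0.781) did not pass.

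**Figure D3:**
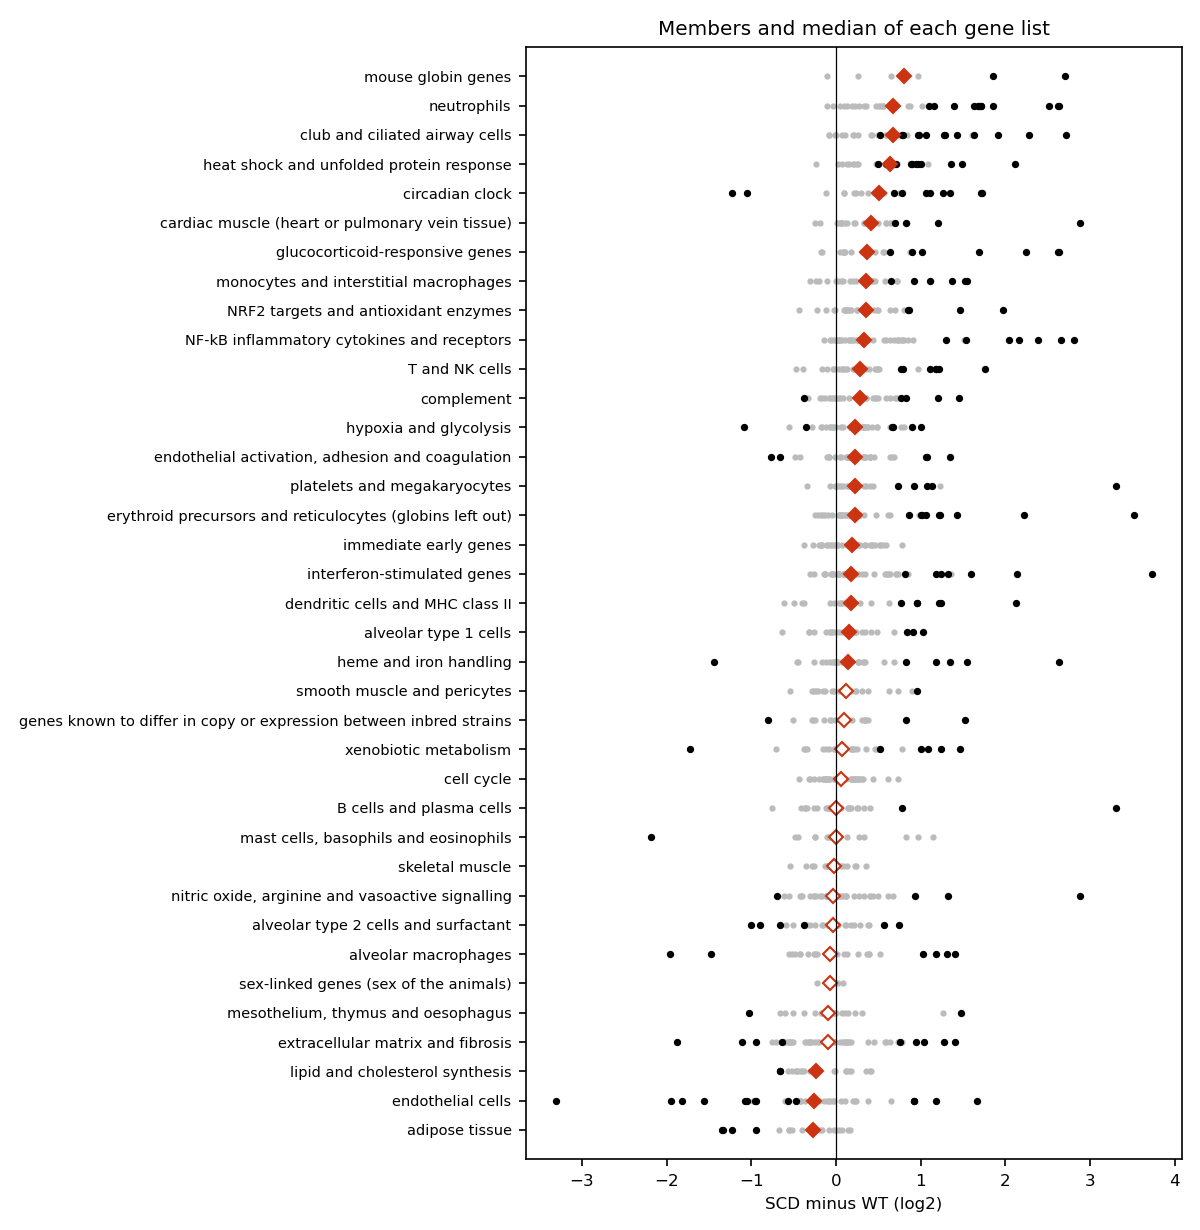
SCD minus WT difference (log2, x axis) of the members of the 37 gene lists (y axis), with black points for members past an adjusted p of 0.05, grey points for the others and diamonds for list medians, filled where camera with its preset correlation passed. Medians run from -0.267 for adipose tissue to 0.805 for globin genes.

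In all, 24 of the 37 lists passed camera, 21 upward and 3 downward, and 23 passed fry; without the intensity trend in camera, as in the first run, 22 passed. With an estimated correlation 0 passed, with 12 lists at an unadjusted p under 0.05. That setting rests on the 2 residual degrees of freedom, so the loss cannot be put down to correlated members alone. The heat shock and neutrophil lists had estimated correlations of -0.035 and -0.025, below the preset 0.01. Their unadjusted camera p still went from 2e-17 and 6.66e-16 to 0.0106 and 0.0115. Other lists had higher estimates, such as 0.347 for NRF2 targets. Lists share members, such as Lcn2, Nppa and Car4, and are not independent of each other.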

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

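No test in this part was chosen only after the result was seen. Probe sets outside the gene comparison, tested together with all others as planned, also differed between the groups in limma at an adjusted p of 0.05. Among transcript clusters without a gene name, 146 were higher and 285 lower in SCD lung. Among probe sets shared by several genes, 27 were higher and 6 lower. These results drew attention as signal in data the gene comparison did not use; no explanation was tested for them.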

How the results depend on the processing

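All 949 calls kept their sign in each alternative that tested them. Each alternative reuses the arrays on which these genes were picked, so the kept signs were largely fixed and add no support. The count of genes changed between SCD and WT lung depended on the SCD arrays: leaving out each array in turn gave from 0 to 786 changed genes, 0 to 643 higher and 0 to 143 lower, with 0 without either SCD replicate (lowest adjusted p of 0.0659 and 0.0695), where the lone array is assumed to vary like the WT arrays. The genes lower in SCD lung numbered 114 without the intensity trend, and the cause was not tested. They numbered 321 without the dimmest 50% of genes and 323 among protein-coding genes, where the genes tested differ by construction. Over every probe set 365 were lower, of which 285 name no gene, 6 name several and 74 name 1 gene, and 430 probe sets that name 1 gene were higher. With the exon control shift removed, which lowers every SCD value, 573 were lower. An adjusted p of 0.10 gave 1752 changed genes (1281 higher, 471 lower), and a log2 difference of at least 1 gave 510 (438 and 72). With an estimated correlation 0 lists passed, 0 higher and 0 lower. The lower lists numbered 5 after repeated quantile normalization and 5 after cyclic loess (the cause was not tested), and 2 to 5 with an array left out; the extracellular matrix and alveolar type 2 lists were added in the first pair of settings and without WT replicate 1 (both 0.013 there). Without the intensity trend 22 lists passed. Apart from the estimated correlation, alveolar type 1 cells lost their call without the trend, with either dim filter, without WT replicate 1 or SCD replicate 1, and with repeated quantile normalization, cyclic loess, the exon control shift removed, protein-coding genes, fry or ranks (adjusted p from 0.0612 to 0.631). Immediate early genes lost theirs without the trend, with either dim filter, without WT replicate 2 or SCD replicate 1, and with cyclic loess, protein-coding genes or ranks (0.052 to 0.143). Lipid synthesis lost its call without WT replicate 2 and with fry (0.0879 and 0.0886). Every other list call was kept where tested; the globin list had too few genes left without the dimmest 50%. Other lists gained were nitric oxide with fry (0.0441), xenobiotic metabolism with the exon control shift removed (0.0441) and alveolar type 2 cells with that shift removed, without the dimmest 50% and with protein-coding genes (0.0154, 0.0352 and 0.0426). With the replicate number as a block, 968 genes changed (775 higher, 193 lower) and 24 lists; deviations of same-numbered arrays had a correlation of -0.002. The block ended the calls of Hc, Csrp3, Retn, Acly and Acaca. Of 122 named genes that passed, 14 missed the threshold without the trend (Cd36, Bmpr2, Scnn1g, Egfl6, Retn, Gsr, Cnn1, Chil1, Csrp3, Cox8b, Hc, Epas1, Acly and Acaca), 26 without WT replicate 1 and 16 without WT replicate 2. Hc and Epas1 missed it with robust eBayes and without identical-value genes, Chil1 with cyclic loess, Hc, Epas1, Acly and Acaca with equal medians, and Chil1, Lrp2, Cnn1, Csrp3, Cox8b and Gsr with the exon control shift removed. Cyclic loess, exon control, identical-value and protein-coding settings were chosen after seeing the data. Probe sets with identical values on all arrays give no direction, and why they are identical was not tested.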

Other observations

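The tests of the clock genes and of neighbours without predicted names were chosen only after the result was seen, as were cyclic loess and the exon control setting. The capillary, pan-endothelial, ciliated, secretory and hepatocyte sets were written with most members' values known and are only described.

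Of 9 general capillary genes, 6 fell (Aplnr, Glp1r, Kit, Tek, Ptprb and Gpihbp1) and 0 rose, with a median of -1.82 and an SD of 1.28 over genes. Of 9 aerocyte genes, Car4 and Apln rose (1.18 ± 0.09 and 0.92 ± 0.09) and 0 fell, with a median of 0.15. Of 15 pan-endothelial genes, Cd34 rose by 1.11 ± 0.13, Cdh5 and Calcrl fell by 0.47 and 0.57, and the median was -0.11. The general capillary set was written with the decreases of most of these genes known, so that it only describes them.

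Immunoglobulin V segments rose in 55 of 190 cases and fell in 0, with a median of 0.78, whereas 1 of 113 T cell receptor V segments rose and 0 fell, with a median of -0.072. Ciliated cell genes rose in 8 of 14 cases (median 0.81; Fam183b by 1.91 and Dynlrb2 by 1.63). Club and mucous secretory genes rose in 5 of 13 (median 0.51), with Muc5b at 1.43 and Muc5ac at 0.20 ± 0.11, which did not pass. Among 16 hepatocyte genes 0 rose and Alb fell by 0.77 ± 0.12, with a median of 0.054; Fgb, the fibrinogen beta chain, stood at 0.10 ± 0.13 beside the increases of Fgg and Fga.

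Clock genes went both ways: those driven through E-box and D-box elements rose in 8 of 14 cases, and those driven through ROR elements fell in 2 of 5 (Arntl and Npas2). With a general upward shift of the SCD arrays as large as that of the exon controls removed, 6 of the 8 higher genes still passed in limma. They ran from Nr1d2 at 0.86 ± 0.09 and Per2 at 0.91 ± 0.10 to Bhlhe40 at 1.52 ± 0.11. A shift of that size is smaller than their differences before removal, from 1.06 (Nr1d2) to 1.72 (Bhlhe40), and so is not the whole of them. These differences were known when the test was chosen, so its outcome was fixed and it adds no further support. The calls of Tef (0.69 ± 0.10 before, 0.49 ± 0.10 after) and Hlf (0.77 ± 0.11 before, 0.58 ± 0.11 after) ended, as the step took 0.196 off each. The arm means differed by 1.264, which a difference in the time of day at collection would give, but the arms were drawn up with these values known. An altered clock in the SCD lung predicts the same, and the tables hold 0 collection times, so these cannot be told apart.

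Called genes neighboured each other: 209 pairs of called genes lay within 3 gene positions, against 87.6 expected from permutations (permutation p = 0.0001, the smallest these permutations can give), with runs such as 8 higher genes around Speer4c and 6 lower genes of the Ifi200 family around Ifi213. By the test set beforehand, 113 pairs of different families, judged by the first 3 letters of the symbol, exceeded the 74.4 expected (permutation p = 0.0001, again the smallest), which argued against paralogs as the whole cause. That rule cannot recognise paralogs under predicted names, such as those in the Speer4 run. Without predicted names, a setting chosen after that result, 47 pairs remained against 40.5 expected (permutation p = 0.173). Paralogs as the whole cause can thus be neither kept nor excluded. With pairs of 1 family left out, 209 pairs against 87.6 became 113 against 74.4, so such pairs made up much of the excess. For segments of another inbred strain carried with the globin genes, 3.11% of 193 genes around the adult globin loci were called against 3.09% of the others (Fisher's exact p = 0.836). These were 6 calls, Trim12a of the strain list among them. With so few calls the test cannot decide on segments at these loci, and it leaves segments elsewhere open. A biological co-regulation of neighbours was not tested.

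More genes were called higher than lower, 79.5% of all calls and 85.9% of those with a log2 difference of at least 1. An intensity-dependent difference between the arrays was argued against as the whole cause, since 71.2% were still higher after cyclic loess. With the exon control shift removed 47.8% of all calls were higher, under the limit of 60% set beforehand, but a constant taken off every SCD value lowers this share by itself and moved the median of all genes to -0.19, so the brighter exon controls are neither supported nor excluded. For the calls of at least 1 on the log2 scale the share was then 62.5%, between limits of 60% and 65% written after the 85.9% and the 47.8% were known, which cannot be told apart either. The excess did not extend to transcript clusters without a gene name. In limma over every probe set these gave 146 higher and 285 lower, against 430 and 74 for probe sets that name 1 gene. Intron controls also moved opposite to exon controls (-0.18 against 0.20), so the gap between their medians was 0.38 wider on the SCD arrays. Whether this bears on the excess was not tested. A true excess of increases among named genes in SCD lung stays open, untested.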
